A study of Mus musculus with 20 samples.

How the data were processed

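Transcriptomes were measured in spermatocytes sorted by flow cytometry from testes of adult mice on a C57BL/6 background, WT or Cxxc1-null. Per the labels' protocols each RNA library was made from 500 cells with Smart-seq2, a full-length cDNA method primed with oligo-dT. There were 12 RNA libraries in 6 groups of 2, at 3 stages (pachytene, diplotene and meiosis II) in both genotypes. The series also lists 8 H3K4me3 ChIP libraries, which were not analysed here. Samples were assigned to groups from their titles. The labels do not say that the 2 libraries of a group came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

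The authors deposited 1 table of FPKM values (fragments scaled by transcript length and library total) for 23235 genes in all 12 libraries. Per the submitters' processing notes, TopHat2 2.1.1 and Cufflinks 2.2.1 were used with the mm9 build. The role of each tool in making these values is not given in the sources used here. FPKM values are not read counts, and no count test was run. The number of sequenced fragments is not given in the sources used here. Ratios of the lowest values between libraries, over genes under 0.3 FPKM in all 12, placed the relative depth of the libraries between 1 and 1.52, but only a minority of the compared genes gave the same ratio, so no read counts were recovered. Values of exactly 0 are reported as listed at 0, and no fold is given against a group listed at 0. Gene symbols are those of the table. The labels describe no strand information, so overlapping and antisense genes are uncertain, as are near-identical gene families such as Slx and Slxl1.

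Values were transformed to log2(FPKM + 1), and 12956 genes with at least 1 FPKM in at least 2 libraries were tested. All 12 libraries entered 1 linear model with a mean per group, fitted with limma 3.58.1 in R 4.3.3, with 6 residual degrees of freedom, moderated variances with a mean-variance trend, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes, and are given ± standard error; FPKM is given as mean ± SD of 2 libraries. Contrasts were Cxxc1-null minus WT within each stage and averaged over stages, the later minus the earlier stage within each genotype, and an F test of the genotype by stage interaction. Tests of 1 value per library used a two-sided exact permutation of the genotype labels within stage, with 216 permutations.

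The design, 24 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes are the 8 largest changes in each direction per stage contrast among genes with adjusted p under 0.05 whose Cxxc1-null libraries both lie on the same side of both WT libraries. The number is 10 for the averaged contrast, with this in all 3 stages, and 5 for each WT stage contrast, and all that pass are named where fewer do. The genes with the 5 smallest interaction p-values and up to 4 members with the smallest p in each list are also named. Uncharacterised transcripts may be summarised. Lists were tested with camera at a preset inter-gene correlation of 0.01 when at least 5 members were tested, then with an estimated correlation, and with fry. The lists cover H3K4 methyltransferase subunits and demethylases, break formation, strand exchange, crossover and mismatch repair, synaptonemal complex, sex body factors, meiotic cell cycle, piRNA pathway, pachytene, spermatid and spermatogonial genes, Sertoli, Leydig, and peritubular, endothelial and blood markers, p53 targets, X-linked housekeeping, Y-linked and X ampliconic genes, DNA methylation enzymes, interferon-stimulated genes, oxidative phosphorylation, ribosomal proteins, and stress response after sorting. The synaptonemal complex list holds BC031353 as an alternative name of Majin, a pairing that the gene table used here does not give. The result of 1 member of the crossover and mismatch repair list is not reported here, so for the genotype contrasts in meiosis II and over stages no member of that list is named. Chromosomes were assigned by gene symbol, then by unambiguous synonym, from a RefSeq table of GRCm38.p6, a different build from mm9, so it was used for chromosome membership and names, with no coordinates. A chromosome was found for 23004 of 23235 genes, with 407 tested on the X and 12448 on the autosomes.

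The model was checked on data simulated from the WT stage means and moderated gene variances of these libraries, in 5 simulations with 200 changed genes among 12956. For the averaged contrast 34.0% of 1.5-fold, 89.0% of 2-fold and 99.4% of 4-fold changes were recovered; for meiosis II 1.49%, 17.3% and 90.6%; for pachytene 0.896%, 20.0% and 91.5%. False calls averaged 6.8, 4 and 4.2 genes. Shifted lists were called in 5 of 5 simulations of each contrast and unshifted lists in 0 of 5 (unadjusted camera p under 0.05). Simulated genes varied independently of each other, so this check could not test lists whose members vary together. Estimated correlations were 0.54 for spermatid and 0.73 for X ampliconic genes. Alternatives were a pseudocount of 0.1, no expression filter, a filter of 5 FPKM, quantile normalization, a common median, a replicate block, no variance trend, a separate fit per contrast, and each library left out in turn. Chosen after the data were seen were fits without short RNA genes, without the 2 libraries that stand apart, and with stages joined by replicate number within genotype.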

Results

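The study compared WT spermatocytes with spermatocytes lacking Cxxc1, which encodes a CpG-binding subunit of the SETD1 H3K4 methyltransferase complexes, at 3 stages of male meiosis. The 12 RNA libraries were 2 WT and 2 Cxxc1-null libraries each of pachytene, diplotene and meiosis II cells, so n = 2 per group throughout. Between 9838 and 11624 genes reached 1 FPKM in a library, and between 4704 and 7227 were listed at 0. Replicates correlated at r = 0.957 to 0.976 across genes. Libraries of different genotype correlated at r = 0.949 to 0.970 in pachytene and 0.955 to 0.974 in diplotene, which overlaps that range. In meiosis II they correlated at 0.941 to 0.953.

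Cxxc1 itself was lower in the Cxxc1-null libraries at every stage. In pachytene the WT mean was 14.5 ± 3.97 FPKM and the Cxxc1-null mean 9.38 ± 0.27 FPKM. This left 64.6% of the WT level. In diplotene the means were 15.6 ± 2.73 and 8.93 ± 0.91 FPKM (57.1%), and in meiosis II 12.7 ± 0.18 and 2.56 ± 0.76 FPKM (20.2%). All 6 Cxxc1-null libraries lay below both WT libraries of their stage, and the stage-averaged log2 difference was -1.08 (exact permutation within stage, p = 0.00926, the smallest the 216 permutations can give). This test takes libraries of different stages as separate, and with stages joined by replicate number within genotype only 6 permutations exist, with a smallest p of 0.333. Within stages, the Cxxc1 change passed the test in meiosis II (log2 fold change -1.96 ± 0.25, limma adjusted p = 0.0024), while the pachytene value of -0.56 ± 0.25 (limma adjusted p = 0.47) and the diplotene value of -0.74 ± 0.25 (limma adjusted p = 0.22) did not. The difference between the meiosis II and pachytene values of Cxxc1 was -1.40 ± 0.36, with a limma adjusted p of 0.15. Which part of the Cxxc1 transcript was deleted is not given in the sources used here, so the remaining FPKM may include transcript outside the deletion.

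**Figure D1:**
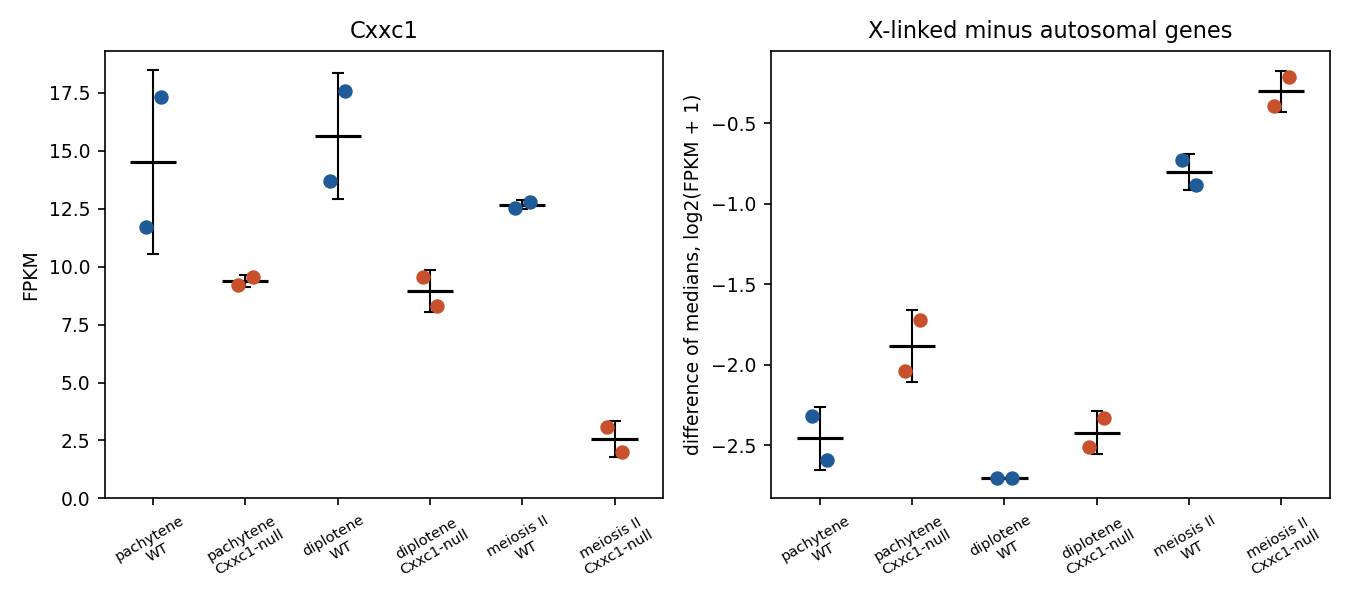
Left, FPKM of Cxxc1 in each of the 12 libraries; right, the median log2(FPKM + 1) of 407 X-linked genes minus that of 12448 autosomal genes in each library. Blue points are WT and orange points Cxxc1-null libraries, with black lines for the mean and bars for the SD of 2 libraries; in every stage both Cxxc1-null points lie below both WT points for Cxxc1 and above them for the X-linked genes.

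Stage dominated the differences between libraries. The first principal component held 60.1% of the variance and separated meiosis II from pachytene and diplotene, the second held 17.3%, and the third held 6.86% and was positive in all 6 WT and negative in all 6 Cxxc1-null libraries. Cxxc1-null diplotene replicate 2 lay nearer meiosis II than the other diplotene libraries (r with the WT meiosis II mean 0.891, against 0.834 to 0.849), and WT pachytene replicate 2 lay nearer diplotene on the second component (6.81, against 51.1 in WT pachytene replicate 1).

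**Figure D2:**
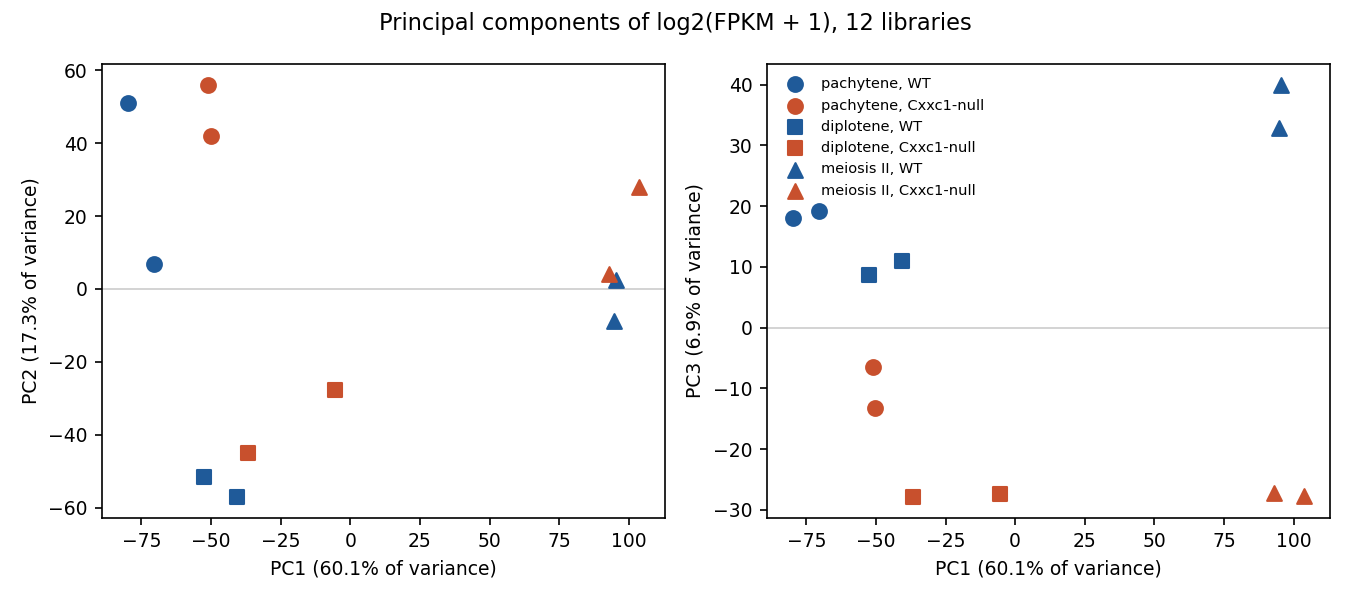
Principal components of log2(FPKM + 1) over 12956 genes, with each point a library, colour for genotype and shape for stage. The first component (horizontal axes) separates meiosis II from the other stages and the third (right, vertical axis) places the 6 WT libraries above 0 and the 6 Cxxc1-null libraries below it.

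In pachytene, Cxxc1-null cells had higher levels of a small set of genes. Cd24a, which encodes a glycosylphosphatidylinositol-anchored surface protein, rose from 1.41 ± 1.03 to 16.1 ± 0.62 FPKM (log2 fold change 2.90 ± 0.30, limma adjusted p = 0.0061). Slco1a6, an organic anion transporter gene, rose from 0.212 ± 0.14 to 5.53 ± 0.0073 FPKM (2.43 ± 0.22). The defensin gene Defb41 rose from 1.17 ± 0.058 to 9.29 ± 2.0 FPKM (2.23 ± 0.22). The X-linked genes Cpxcr1, 4933436I01Rik and 4930428D18Rik rose by log2 2.57 ± 0.36, 2.81 ± 0.45 and 2.45 ± 0.42, and the uncharacterised transcripts 9530002B09Rik and 2610016A17Rik by 2.60 ± 0.25 and 2.81 ± 0.37. Of the genes that fell, Maz, a zinc finger transcription factor gene, went from 25.7 ± 9.8 to 5.03 ± 0.30 FPKM (log2 fold change -2.10 ± 0.34, limma adjusted p = 0.044), and the uncharacterised 1700010B08Rik had a log2 fold change of -1.32 ± 0.20. In all, 44 genes rose and 2 fell of 12956 tested in limma, with 1388 at an unadjusted p under 0.05. This count rests on each library: it was 9 without WT replicate 1, 21 without WT replicate 2 and 1 without either Cxxc1-null replicate, and 12 without both libraries that stand apart. It was 86 with a pseudocount of 0.1, 28 above 5 FPKM, 9 without an expression filter and 6 in a separate fit.

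By gene list, camera placed 7 of 24 lists higher and 1 lower in Cxxc1-null pachytene, and none of these calls held with an estimated correlation. Spermatid genes had a median log2 fold change of 0.37 with 29 of 35 members positive (camera adjusted p = 0.0059; adjusted p = 0.64 with an estimated correlation), and X ampliconic genes a median of 1.72 with 6 of 7 positive (camera adjusted p = 0.0059; 0.61 as the adjusted p with an estimated correlation). Markers of other testicular cells were also higher in camera: Sertoli markers had a median of 0.35 and peritubular, endothelial and blood markers 0.38 (camera adjusted p = 0.015 and 0.018; adjusted p = 0.61 for both with an estimated correlation). X-linked housekeeping genes had a median of 0.36, oxidative phosphorylation genes 0.25, and ribosomal protein genes 0.26 (camera adjusted p = 0.018, 0.03 and 0.03; adjusted p = 0.62, 0.64 and 0.78 with an estimated correlation). The piRNA pathway was lower, with a median of -0.14 (camera adjusted p = 0.024; adjusted p = 0.61 with an estimated correlation). No member of these 8 lists passed limma over all genes, and adjusted over the list alone 2 spermatid, 2 Sertoli, 1 peritubular, endothelial and blood and 4 X ampliconic members did. The number of lists was 3 under quantile normalization and without an expression filter, and 2 without WT replicate 1 or without Cxxc1-null replicate 2.

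Diplotene showed a larger set than pachytene in the main fit, again mostly higher. That order did not hold in a separate fit per contrast, with 4 calls in diplotene and 6 in pachytene. Cd24a rose from 2.51 ± 0.70 to 22.2 ± 2.7 FPKM (log2 fold change 2.74 ± 0.30, limma adjusted p = 0.006) and Gchfr, which encodes the feedback regulator of GTP cyclohydrolase 1, from 2.91 ± 0.15 to 21.1 ± 5.7 FPKM (2.48 ± 0.27, limma adjusted p = 0.006). The transcripts 2610016A17Rik, 4930428D18Rik and 4933436I01Rik rose again, by 2.93 ± 0.37, 2.47 ± 0.42 and 2.46 ± 0.45. Among genes that fell were the transcription factor genes Emx2 (7.91 ± 0.21 to 1.98 ± 0.15 FPKM, log2 fold change -1.58 ± 0.24), Pax9 (4.20 ± 0.90 to 0.715 ± 0.089 FPKM, -1.59 ± 0.27) and Zkscan17 (43.7 ± 18 to 9.76 ± 2.6 FPKM, -2.01 ± 0.38). Phf13, which encodes a PHD finger protein, fell from 34.0 ± 8.0 to 9.45 ± 1.6 FPKM (-1.73 ± 0.30), the formin gene Fmnl1 from 4.63 ± 0.94 to 0.486 ± 0.036 FPKM (-1.91 ± 0.34), and the ribonuclease P subunit gene Rpp21 from 207 ± 54 to 63.3 ± 21 FPKM (-1.71 ± 0.31). The uncharacterised 1700010B08Rik and 4933439C10Rik fell by 1.58 and 1.55 on the log2 scale. The small RNA genes Mir487b, Mir5113 and Scarna8 were listed at 0 in both WT diplotene libraries. In the 2 Cxxc1-null ones they had 189 and 101, 85.2 and 73.1, and 17.7 and 18.9 FPKM. The libraries were primed with oligo-dT, so whether FPKM of such genes measures the small RNAs themselves is not known.

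In limma 91 genes rose and 11 fell in Cxxc1-null diplotene, with 1747 at an unadjusted p under 0.05. The share that rose, 89.2%, was 73.3% under quantile normalization and 76.8% with a common median. The number called was 4 without WT replicate 1, 6 without WT replicate 2, 480 without Cxxc1-null replicate 1, 7 without Cxxc1-null replicate 2, and 13 without both libraries that stand apart. It was 212 with a pseudocount of 0.1, 60 above 5 FPKM, 50 without an expression filter, 45 under quantile normalization, 4 in a separate fit, and 164 with short RNA genes left out. Camera placed spermatid genes (median 0.83, 28 of 35 positive), X ampliconic genes (1.41, 7 of 7 positive) and Y-linked genes (0.51, 5 of 5 positive) higher and pachytene genes (-0.18, 6 of 20 positive) lower (adjusted p = 0.026, 0.0022, 0.041 and 0.041; adjusted p = 0.97, 0.97, 0.80 and 0.80 with an estimated correlation). Of their members, the Y-linked translation initiation factor gene Eif2s3y passed limma, rising from 1.72 ± 0.44 to 5.89 ± 1.7 FPKM (log2 fold change 1.33 ± 0.24, adjusted p = 0.038). The number of lists called was 0 without Cxxc1-null replicate 2, the library nearest meiosis II, and 0 without WT replicate 1. It was 2 above 5 FPKM and 2 with a common median.

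Meiosis II held the most changes of the 3 stages. Steap1, a metalloreductase family gene, rose from 6.27 ± 2.1 to 52.7 ± 11 FPKM (log2 fold change 2.90 ± 0.31, limma adjusted p = 0.0014), Vgll2, a transcription cofactor gene, from 0.132 ± 0.19 to 10.1 ± 4.1 FPKM (3.25 ± 0.36), and Rbpms2, an RNA-binding protein gene, from 1.33 ± 0.49 to 15.5 ± 2.4 FPKM (2.83 ± 0.23). Fam57a, the sulfotransferase gene Sult2a3, Gkn2 and 2610016A17Rik rose by 2.91 ± 0.29, 2.82 ± 0.28, 2.71 ± 0.27 and 4.41 ± 0.37. Fmnl1 fell from 10.7 ± 1.3 to 0.566 ± 0.14 FPKM (-2.90 ± 0.34, limma adjusted p = 0.0017) and the kallikrein-related gene Klk1b8 from 19.8 ± 0.14 to 2.47 ± 2.1 FPKM (-2.73 ± 0.43). The uncharacterised 4921530L21Rik and 1700027A15Rik fell by 2.72 and 2.70 on the log2 scale. Mir135b was listed at 0 in both WT libraries and had 43.8 and 101 FPKM in the Cxxc1-null ones. Mir3473d, Mir425, Mir3063 and Mir92b were listed at 0 in both Cxxc1-null libraries. In the WT ones they had 110 and 204, 85.4 and 238, 264 and 69.0, and 96.5 and 180 FPKM.

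Across all genes tested, limma called 795 higher and 563 lower in Cxxc1-null meiosis II, of which 465 and 361 changed at least 2-fold, and 3385 genes had an unadjusted p under 0.05. The count was 401 and 597 without WT replicate 1 and 2, 551 and 422 without Cxxc1-null replicate 1 and 2, 732 above 5 FPKM, and 219 in a separate fit. The share higher, 58.5%, was 71.8% and 49.2% without WT replicate 1 and 2 and 50.3% above 5 FPKM, so the balance of rises and falls is uncertain. Among 31 meiotic cell cycle genes 4 fell: Espl1, which encodes separase (19.2 ± 3.3 to 6.22 ± 0.76 FPKM, log2 fold change -1.48 ± 0.31), Cdk1 (46.3 ± 10 to 16.8 ± 0.92 FPKM, -1.40 ± 0.32), the anaphase-promoting complex activator Cdc20 (-1.30 ± 0.30) and the checkpoint kinase gene Bub1b (-1.09 ± 0.29). Sgol1, a centromeric cohesin protector gene, rose (0.83 ± 0.21), and 26 did not pass. Adjusted over the list alone 1 rose and 6 fell. The list was lower in camera with a median of -0.40 (adjusted p = 0.033; adjusted p = 0.92 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.48 with 37 of 40 positive, of which Ndufa9 (0.83 ± 0.22) and Ndufs3 (0.67 ± 0.18) passed, and ribosomal protein genes a median of 0.48 with 75 of 83 positive and 0 passing (camera adjusted p = 0.00022 and 2.1e-05; adjusted p = 0.88 and 0.99 with an estimated correlation). The number of lists called was 5 without an expression filter and 5 without both libraries that stand apart, neither of which is a meiosis II library.

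The title of the series concerns crossover formation, and no gene of the break formation (11 tested), strand exchange (32), crossover and mismatch repair (18) or synaptonemal complex (17) lists passed limma in pachytene or diplotene, over all genes or adjusted over the list alone. Their medians lay between -0.17 and 0.03 in pachytene and between -0.04 and 0.16 in diplotene, and none was called by camera. Few genes of any kind passed at these stages (46 and 102 of 12956). In simulated pachytene data only 0.896% of 1.5-fold and 20.0% of 2-fold changes were recovered. The absence of calls in these lists is therefore weak evidence that their genes did not change. The break-forming enzyme gene Spo11 had 146 ± 33 FPKM in WT and 176 ± 23 FPKM in Cxxc1-null pachytene (log2 fold change 0.29 ± 0.34), the axis gene Hormad1 0.13 ± 0.49, and the central region gene Sycp1 -0.53 ± 0.33. These 3 were chosen after their values were seen. In meiosis II the crossover and mismatch repair list was not called by camera (median 0.02, adjusted p = 0.96). Few members of the other 3 lists passed limma, with calls in both directions only among strand exchange genes. Of strand exchange genes Palb2 rose (0.86 ± 0.19) and Xrcc2 fell (-1.12 ± 0.26), of break formation genes Ccdc36 fell (-1.05 ± 0.29), and of the synaptonemal complex list BC031353, whose place there is uncertain, fell (-1.16 ± 0.21). In the stage-averaged contrast Psmc3ip (0.47 ± 0.11) and Syce1 (0.44 ± 0.11) rose, Xrcc2 (-0.64 ± 0.15) and BC031353 (-0.51 ± 0.12) fell, and 0 of 11 break formation genes passed limma. None of these 4 passed limma with stages joined by replicate number (adjusted p = 0.185 or above).

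Averaged over the 3 stages, 1493 genes rose and 665 fell in limma, with 4178 at an unadjusted p under 0.05. If the same-numbered libraries of a genotype came from 1 animal, the stages are not separate evidence: with each genotype and replicate number joined to 1 mean over stages (4 units, 2 residual degrees of freedom), 434 genes passed, 80.9% of them higher. All 20 genes named next passed there too. The changes that rose most included 2610016A17Rik (3.38 ± 0.21), Cd24a (2.65 ± 0.18, limma adjusted p = 4.6e-05), Steap1 (2.45 ± 0.18), Slco1a6 (2.39 ± 0.13, limma adjusted p = 1.6e-05) and Gchfr (2.31 ± 0.16), with 4933436I01Rik, 4930461G14Rik, Gm5800, Cypt2-ps and 4930428D18Rik between 1.98 and 2.31. Genes that fell included Fmnl1 (-1.89 ± 0.20), Zkscan17 (-1.87 ± 0.22), Agr3 (-1.66 ± 0.24), Phf13 (-1.60 ± 0.17), Klk1b8 (-1.58 ± 0.25), Emx2 (-1.58 ± 0.14, limma adjusted p = 0.00017) and Maz (-1.58 ± 0.20), with 1700096J18Rik at -1.73 and 1700012A03Rik at -1.53. Mir3473d, which was at 0 in both Cxxc1-null meiosis II libraries, also fell. The share that rose, 69.2%, was 51.1% under quantile normalization and 58.8% with a common median. Leaving out Cxxc1-null pachytene replicate 1 or 2 gave 1413 or 1328 calls. Leaving out WT diplotene replicate 1 or 2 gave 1382 or 1359, Cxxc1-null diplotene replicate 2 gave 1437. Leaving out WT meiosis II replicate 1 gave 1397, Cxxc1-null meiosis II replicate 2 gave 1287, and leaving out both libraries that stand apart gave 1291.

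**Figure D3:**
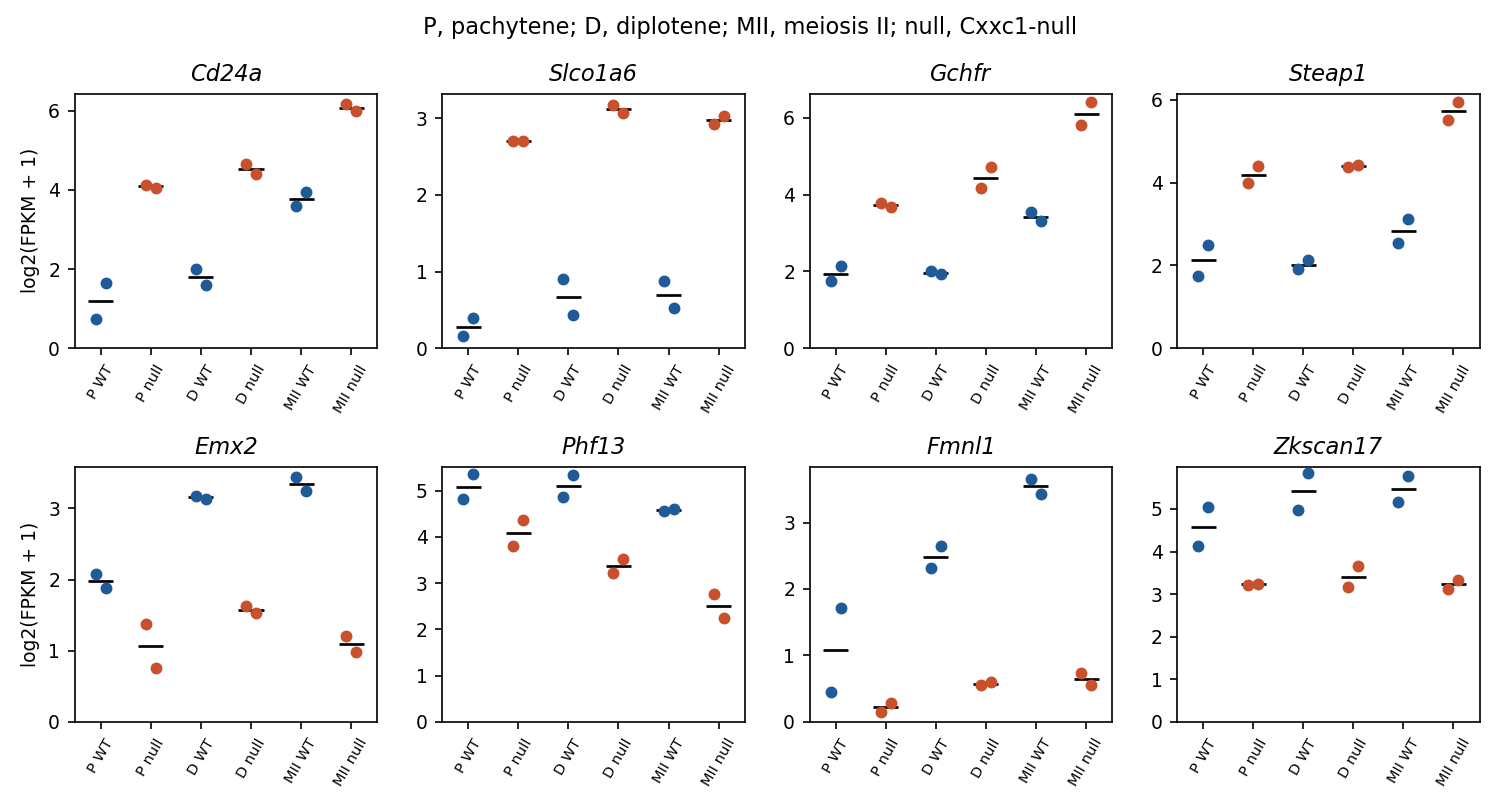
log2(FPKM + 1) per library of 4 genes that rose (top) and 4 that fell (bottom) in the stage-averaged contrast, with blue points for WT, orange points for Cxxc1-null libraries and black lines for the mean of 2 libraries. Both Cxxc1-null points lie on the same side of both WT points in each stage.

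In the stage-averaged contrast, 6 of 7 X ampliconic genes rose, among them the actin-related gene Actrt1 (1.35 ± 0.20), Cypt1 (1.97 ± 0.37), Slxl1 (1.56 ± 0.29) and Slx (0.64 ± 0.16), with a list median of 1.35; Slx and Slxl1 are near-identical copies. Of 5 Y-linked genes 2 rose, Eif2s3y (1.07 ± 0.14) and the zinc finger gene Zfy2 (0.84 ± 0.15), with a median of 0.53. Oxidative phosphorylation genes had a median of 0.31 and 6 of 40 rose, such as Ndufa9 (0.63 ± 0.13) and Ndufv2 (0.57 ± 0.13), and ribosomal protein genes had a median of 0.26 and 4 of 83 rose, such as Rps12 (0.81 ± 0.19). Of all 12956 tested genes 1493 rose. The share of oxidative phosphorylation genes that rose was near that, and the share of ribosomal protein genes was below it. Of 19 piRNA pathway genes 4 fell, including Pld6 (-0.71 ± 0.14), Tdrd6 (-0.71 ± 0.15) and the PIWI gene Piwil1 (-0.49 ± 0.13), and 2 rose, Tdrkh (0.49 ± 0.12) and Gtsf1 (0.59 ± 0.18), with a median of -0.23. Pachytene genes had a median of -0.15, with 2 of 20 lower, the testis linker histone gene Hist1h1t (-0.70 ± 0.18) and Piwil1. These 6 lists were called by camera (adjusted p = 0.002, 0.024, 0.002, 0.0034, 0.029 and 0.031) and none was with an estimated correlation (adjusted p = 0.87, 0.58, 0.89, 0.89, 0.58 and 0.58); fry, which tests against no change, called the Y-linked list (adjusted p = 0.0058). Adjusted over each list alone, 6 X ampliconic, 4 Y-linked, 8 oxidative phosphorylation and 0 ribosomal protein genes were higher, 8 piRNA genes were lower and 2 higher, and 2 pachytene genes were lower. With stages joined by replicate number, Actrt1, Cypt1, Slxl1 and Eif2s3y passed limma again, while Slx, Zfy2 and the named oxidative phosphorylation, ribosomal protein, piRNA and pachytene genes that were tested there did not. The number was 3 without WT pachytene replicate 1, WT diplotene replicate 1 or Cxxc1-null diplotene replicate 2, and 2 without Cxxc1-null pachytene replicate 2.

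The other 18 lists were not called in that contrast. Of the genes named here and tested again with stages joined by replicate number, Cxxc1, Catsper3, Prm2, Id4, Dhh, Cd14, Emr1 and Hspb1 passed limma and the others did not. Spermatid genes split, with 6 higher, including Catsper3 (1.32 ± 0.28), Spaca1 (1.16 ± 0.26) and Catsper4 (0.92 ± 0.21), and the protamine gene Prm2 lower (-1.60 ± 0.44). Among H3K4 methyltransferase subunits Cxxc1 and Mll2 (-0.46 ± 0.13) fell and 10 of 12 did not pass, and among H3K4 demethylases Kdm5b fell (-0.46 ± 0.11). Of DNA methylation enzymes Uhrf2 (0.58 ± 0.14) and Dnmt3l (0.62 ± 0.15) rose and Mbd1 fell (-0.71 ± 0.16). Of spermatogonial genes Upp1 (0.68 ± 0.14) and Nanos3 (1.10 ± 0.29) rose with Dnmt3l, while Id4 (-1.04 ± 0.15) and Prss50 (-0.53 ± 0.12) fell. Markers of other cells that rose were Dhh (1.14 ± 0.14) of 11 Sertoli markers and Cd14 (1.10 ± 0.11) and Emr1 (0.59 ± 0.11) of 9 peritubular, endothelial and blood markers, and 0 of 7 Leydig markers passed limma. Of p53 targets Pmaip1 (0.60 ± 0.12) and Casp8 (0.31 ± 0.08) rose, and of stress response genes Hspb1 (1.42 ± 0.18) and Ier3 (0.69 ± 0.18) rose. Of cell cycle genes Cdc25c (0.63 ± 0.17) rose and Espl1 (-0.92 ± 0.18) and Cdc20 (-0.66 ± 0.17) fell. Of X-linked housekeeping genes Med14 (0.46 ± 0.10), Rbmx (0.67 ± 0.15) and Uba1 (0.68 ± 0.18) rose. No sex body factor (17 tested, median -0.06) or interferon-stimulated gene (8 tested, median -0.07) passed limma.

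X-linked genes as a whole were higher in Cxxc1-null libraries than in WT at each stage. The median log2(FPKM + 1) of 407 X-linked genes minus that of 12448 autosomal genes was -2.46 ± 0.19 in WT and -1.88 ± 0.22 in Cxxc1-null pachytene, -2.70 ± 0.0015 and -2.42 ± 0.13 in diplotene, and -0.80 ± 0.11 and -0.30 ± 0.13 in meiosis II (SD, n = 2 libraries). All 6 Cxxc1-null libraries lay above both WT libraries of their stage, with a mean difference of 0.45 (exact permutation within stage, a test chosen after the data were seen that takes stages as separate, p = 0.00926, the smallest possible). Per gene, the median X-linked log2 fold change exceeded the autosomal one by 0.40 in pachytene, 0.26 in diplotene, 0.44 in meiosis II and 0.36 averaged (camera p = 1.4e-21, 2.8e-10, 2.8e-06 and 1.7e-14; adjusted p = 0.13, 0.18, 0.31 and 0.12 with an estimated correlation). The gene-level excess over other genes was therefore called only at the preset correlation. Against no change, which is no comparison with other genes, fry gave X-linked genes an adjusted p of 0.035, 0.035, 0.074 and 0.003. In pachytene, Sertoli markers (median 0.35, 10 of 11 positive) and peritubular, endothelial and blood markers (0.38, 8 of 9 positive) were higher alongside. In the averaged contrast 171 X-linked genes rose and 4 fell in limma, or 42.0% higher against 10.5% of autosomal genes. These shares take libraries of different stages as separate. The diplotene excess was 0.12 without Cxxc1-null diplotene replicate 2, the pachytene excess 0.25 without Cxxc1-null pachytene replicate 2, and the meiosis II excess 0.25 without Cxxc1-null meiosis II replicate 2. Without an expression filter, which adds genes at or near 0, the excess was 0.068 in pachytene, 0.0066 in diplotene and 0.063 in meiosis II, and with a minimum of 5 FPKM it was 0.80, 0.71 and 0.64. With a pseudocount of 0.1 it was 0.92, 0.94 and 0.53, and 0.78 averaged, so its size depends on how low values are treated.

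**Figure D4:**
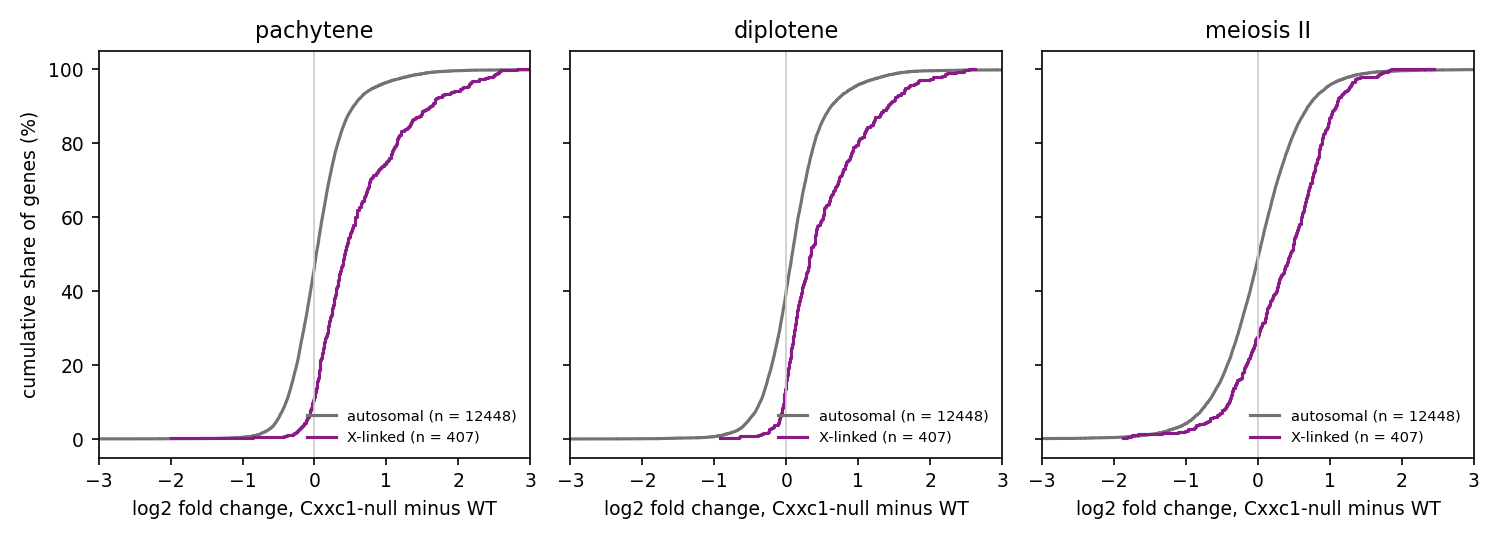
Cumulative share of genes (vertical axis, percent) by log2 fold change of Cxxc1-null minus WT (horizontal axis) for 407 X-linked (purple) and 12448 autosomal genes (grey) at each stage. The X-linked curve lies to the right, with medians of 0.43, 0.34 and 0.45 against 0.03, 0.08 and 0.01.

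Genotype effects at different stages, which share no library, were compared with each other. Across 12956 genes, which are not independent replicates, log2 fold changes correlated at r = 0.57 between pachytene and diplotene, 0.32 between pachytene and meiosis II and 0.45 between diplotene and meiosis II. Between pachytene and diplotene 24 genes rose in both, against 0.31 for independent lists, between pachytene and meiosis II 31 against 2.70. Between diplotene and meiosis II it was 71 against 5.58, with 10 against 0.48 that fell. The contrasts share the same variance estimate per gene, and same-numbered libraries of a genotype may share a source. Both can raise the overlaps, and a shared source also the correlations, so the values for independent lists are no strict reference. The F test of genotype by stage in limma called 7 genes, with 1136 at an unadjusted p under 0.05. Of these, 5 were small RNA genes at 0 in 10 or more libraries (Mir5113, Scarna8, Mir487b, Mir92b and Mir135b), and the other 2 were Defb5 and Slc25a43. Groups with both libraries at 0 add no spread, which can make the p-values of such genes too small. The count was 2 with short RNA genes left out, 28 without an expression filter, and 14 without both libraries that stand apart; without 1 library it was 11 (WT pachytene replicate 2 or either Cxxc1-null diplotene replicate) or 14 (WT meiosis II replicate 2).

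From pachytene to diplotene in WT, a part of the synaptonemal complex, strand exchange and spermatogonial genes fell. Of 17 synaptonemal complex genes 8 fell, including Sycp1 (-2.60 ± 0.33) and Tex12 (-3.14 ± 0.48), as did 16 of 32 strand exchange genes, including the recombinase gene Dmc1 (-2.56 ± 0.40), while 3 rose, and 9 of 17 spermatogonial genes, including Sohlh2 (-3.24 ± 0.27) and Stra8 (-1.93 ± 0.20). Of 31 cell cycle genes 4 fell and 10 rose, among them the Aurora kinase gene Aurkb (1.51 ± 0.30). By the rule for single genes, Zmynd15, a transcriptional repressor gene (3.24 ± 2.7 to 21.4 ± 0.83 FPKM), and Rhcg, an ammonium transporter gene (8.34 ± 7.1 to 38.5 ± 3.9 FPKM), rose most after the small RNA genes Mir3968, Mir425 and Mir669h. The largest falls were small RNA genes (Snord49b, Mir1956, Snora68, Snora33 and Mir3091). Limma called 1177 genes higher and 2254 lower. The share that rose, 34.3%, was 50.1% under quantile normalization and 58.3% with a common median. It was lower without WT pachytene replicate 1 or either WT diplotene replicate, and higher without WT pachytene replicate 2. The count was 1501 without WT pachytene replicate 1, 1784 and 1335 without WT diplotene replicate 1 and 2, and 3 in a separate fit with 2 residual degrees of freedom. Camera called 8 lists, 1 higher and 7 lower, and 0 with an estimated correlation (adjusted p = 0.40 or above).

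From diplotene to meiosis II, spermatid and sex-linked transcripts rose in the WT libraries, and so did markers of some other cells and of sorting stress. All 11 Sertoli markers rose (median 2.28), as did 6 of 9 peritubular, endothelial and blood markers and 10 of 15 stress response genes, while 2 stress response genes fell. Leydig markers were not called (2 of 7 higher, 1 lower, camera adjusted p = 0.43). Of 35 spermatid genes 31 rose, such as Catsper4 (2.60 ± 0.77 to 67.6 ± 8.2 FPKM, log2 fold change 4.26 ± 0.37) and the sperm-egg fusion gene Izumo1 (4.23 ± 0.41), with a median of 4.16. Of 407 X-linked genes 365 rose and 1 fell, with a median of 2.03, a call that held with an estimated correlation (adjusted p = 0.039), and all 5 Y-linked genes rose, such as Eif2s3y (3.97 ± 0.24). Of 19 piRNA genes 12 fell, including Tdrd1 (-2.71 ± 0.19) and Piwil1 (-2.76 ± 0.23), and 1 rose, and of 18 crossover genes 6 fell, including Ccnb1ip1 (-3.16 ± 0.36), and 1 rose. Of 17 synaptonemal complex genes 7 fell and 2 rose, the cohesin genes Rec8 (3.76 ± 0.42) and Smc3 (2.43 ± 0.23). Cst12 and Clu rose by 5.78 ± 0.56 and 5.32 ± 0.54 and Aym1 fell from 50.3 ± 15 to 2.80 ± 1.0 FPKM. The other genes the rule named were small RNA genes, higher for Mir1956, Mir3063 and Mir92b and lower for Mir1892, Mir669h, Snora62 and Scarna3b. Limma called 3382 genes higher and 2453 lower; the share that rose, 58.0%, was 40.4% under quantile normalization and 40.9% with a common median. Camera called 14 lists, 7 in each direction, and 0 with an estimated correlation (adjusted p = 0.23 or above).

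The stage changes of Cxxc1-null and WT cells correlated at r = 0.83 from pachytene to diplotene and 0.88 from diplotene to meiosis II over 12956 genes. From pachytene to diplotene 3794 genes were called and from diplotene to meiosis II 5719. Of the genes called in WT, 99.5% had the same sign in Cxxc1-null cells at the first step (slope 0.85, r = 0.93) and 98.7% at the second (slope 0.80, r = 0.94), with 885 and 2840 called higher in both genotypes and 1755 and 1759 lower. The spermatid list had a median rise of 2.99 from diplotene to meiosis II in Cxxc1-null cells, against 4.16 in WT. Cxxc1-null minus WT, the list median was 0.83 in diplotene and -0.14 in meiosis II, so the smaller rise lies partly in a higher diplotene level. That level includes Cxxc1-null diplotene replicate 2, the library nearest meiosis II. The Cxxc1-null shares that rose, 40.6% and 57.3%, were 51.7% and 45.6% under quantile normalization, and the first was 55.7% with a common median. The first share was lower without Cxxc1-null pachytene replicate 2 or either Cxxc1-null diplotene replicate, so it is uncertain both ways. The Cxxc1-null pachytene to diplotene count was 2435 and 444 without pachytene replicate 1 and 2, and 1239 and 1965 without diplotene replicate 1 and 2.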

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

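Each test in this part was written down before its own value was computed, after the pattern it bears on had been seen; the fit without Cxxc1-null diplotene replicate 2, the permutation of X-linked medians, the fit with stages joined by replicate number and the values of Prm1 were chosen after the data were seen.

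The genotype effect differed between stages for 7 genes in the limma F test. The adjusted p was 5.06e-07 for Mir5113, 3.02e-06 for Scarna8, 5.63e-06 for Mir487b and for Mir92b, and 0.000123 for Mir135b. Defb5 (adjusted p = 0.000791) was listed at 0 in all libraries but the Cxxc1-null meiosis II ones, where it had 2.91 ± 0.28 FPKM, and Slc25a43 (adjusted p = 0.0153) had 3.99 ± 0.61 FPKM in WT and 0.483 ± 0.18 FPKM in Cxxc1-null meiosis II and under 0.1 FPKM in every pachytene and diplotene library. A group with both libraries at 0 adds no spread to the variance estimate. The small RNA genes and Defb5 were at 0 in most libraries. Their p-values therefore rest largely on zeros and can be too small as a measure of the spread between libraries.

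The genotype effect of 6 gene groups also differed between stages in camera, and none did with an estimated correlation. The median difference, diplotene minus pachytene, was -0.20 for Sertoli markers, -0.48 for Leydig markers, -0.14 for ribosomal protein genes and -0.073 for X-linked genes. Meiosis II minus diplotene, it was -1.09 for spermatid genes, 0.26 for oxidative phosphorylation genes and 0.36 for ribosomal protein genes. Meiosis II minus pachytene, it was -0.82 for spermatid genes, -0.47 for Sertoli markers and 0.24 for ribosomal protein genes. The adjusted p with an estimated correlation was 0.43 or above for each of them.

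Higher X-linked transcripts in Cxxc1-null cells could come from cells of later stages carried into the sorts, since X-linked genes rise by a median of 2.03 from diplotene to meiosis II. In pachytene, the X-linked median of 0.43 exceeded that of autosomal genes matched on WT level and on that rise (0.28) by 0.144, with a highest of 10000 matched draws of 0.396, and in diplotene without Cxxc1-null replicate 2 the excess was 0.0775. In meiosis II the excess was 0.448 over genes matched on mean level over all 12 libraries. That argues against a rise of genes of low mean level as the whole cause there. Genes were not matched on their meiosis II level, so a rise of genes low in meiosis II itself stays open. These draws, too, sample genes and not libraries. In pachytene the excess over genes matched on the mean over all 12 libraries was 0.39, which decides nothing. That mean includes meiosis II, where X-linked genes are higher, so the matched genes need not be low in pachytene. Carry-over stays open in pachytene and diplotene, since the draws sample genes and not libraries. The pachytene excess of 0.144 is below the SD between libraries (0.19 and 0.22), and the diplotene value rests on 1 Cxxc1-null library. The bound set for the carry-over tests was thus too weak. Also open and not tested are somatic cells in the sorts, and the hypothesis that loss of Cxxc1 weakens the silencing of sex-linked genes. Sertoli markers had medians of 0.35 in pachytene, 0.03 in diplotene and -0.27 in meiosis II. In the stage average Dhh rose of 11 Sertoli markers, and Cd14 and Emr1 of 9 peritubular, endothelial and blood markers. Of 7 Leydig markers 0 rose, and of all 12956 tested genes 1493 did. Camera called none of these lists there (adjusted p = 0.63, 0.63 and 0.82), so Dhh, Cd14 and Emr1 alone do not point to somatic cells.

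The 1358 calls in meiosis II might reflect another mix of meiosis II cells and spermatids in the sort. The test chosen for it compared the genotype effect with the WT change from diplotene to meiosis II across genes (r squared 2.66e-05 at most), but a mix with spermatids moves genes along the difference between meiosis II cells and spermatids, which no library measures, so the bound set for that test was wrong and it decides nothing. The mix stays open, as does an effect of Cxxc1 loss on the cells themselves: the spermatid list had a median of -0.14 in Cxxc1-null meiosis II with 10 of 35 positive and 0 called (camera adjusted p = 0.25), and Prm1, at 337 and 1000 FPKM against 2213 and 3794 FPKM in WT, did not pass limma (adjusted p = 0.091). For the stage-averaged count, 1 of 100 splits drawn from the 108 possible within-stage splits gave as many calls as the genotypes, the real split itself, with 2158 calls against 540 in the highest other, so chance is excluded at the 0.05 level only if libraries of different stages are separate; with stages joined by replicate number 434 genes were called and the splits are too few for such a share.

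Small RNA genes, which held several of the largest folds and 5 of the 7 stage differences, may rest on few fragments, because their transcripts are shorter than a library fragment. The median residual SD of the 108 tested was 9.57 times that of other genes of like mean level, and 75 of them were listed at 0 in 6 or more libraries. That is what this explanation predicts for the 108 genes as a set, and no biological explanation was tested. The ratio does not bear on the 5 genes with stage differences. Their standard errors were small, from 0.13 (Scarna8 in diplotene) to 0.30 (Mir135b in meiosis II), as they were at 0 in most libraries. Whether FPKM of small RNA genes measures the small RNAs themselves, in libraries primed with oligo-dT, is also open.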

How the results depend on the processing

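The fits with short RNA genes left out, with stages joined by replicate number, and without Cxxc1-null diplotene replicate 2 and WT pachytene replicate 2 were chosen after the data were seen; the other settings were planned. No result of a named gene reversed, but nearly all of these were named because they passed in the main fit. Of 328 such results, 304 held their side of the threshold under quantile normalization and 304 with a common median. With a pseudocount of 0.1, 311 held, without a filter 282 and without a variance trend 327, and in each setting the rest weakened. The majority direction of calls did turn in stage contrasts. From WT pachytene to diplotene 34.3% of calls were higher, and 58.3% with a common median. Over all single libraries left out, 1376 of 1880 held and 504 weakened. The X-linked excess kept its direction, and its call at the preset correlation, in every setting run, but not with an estimated correlation (adjusted p = 0.13, 0.18, 0.31 and 0.12 in pachytene, diplotene, meiosis II and the stage average). The Cxxc1 level kept its direction with a pseudocount of 0.1 and with each library left out. Counts of calls moved more, and the cause was not tested beyond the change in genes or libraries each setting makes. Pachytene calls (46) were 86 with a pseudocount of 0.1, 9 without a filter, 28 above 5 FPKM, 6 in a separate fit and 12 without the 2 libraries that stand apart. Diplotene calls (102) were 212, 50, 60, 4 and 13 in those settings, 45 under quantile normalization and 164 with short RNA genes left out. Meiosis II calls (1358) were 732 above 5 FPKM and 219 in a separate fit, WT pachytene to diplotene calls (3431) were 3 in a separate fit, and stage-averaged calls (2158) were 1291 without the 2 libraries that stand apart and 434 with stages joined by replicate number, where 32 of 71 named results held and 39 weakened. Genotype by stage calls (7) were 28 without a filter, 2 with short RNA genes left out and 14 without the 2 libraries that stand apart. Lists called in pachytene (8) were 3 without a filter and 3 under quantile normalization; in diplotene (4) they were 2 above 5 FPKM, 2 with a common median and 0 without the 2 libraries that stand apart; in meiosis II (3) they were 5 without a filter and 5 without those libraries. Leaving out 1 library at a time, where the lone library left in a group is assumed to vary like the other groups, gave 1 to 21 pachytene, 4 to 480 diplotene, 401 to 597 meiosis II and 1287 to 2585 stage-averaged calls, 1335 to 4115 WT and 444 to 2435 Cxxc1-null pachytene to diplotene calls, 6 to 14 genotype by stage calls, and 2 to 9, 0 to 5 and 2 to 8 lists in pachytene, diplotene and the stage average. Scaling (quantile normalization, then common median) moved the median of all genes by -0.13 and -0.13 in diplotene, 0.15 and 0.20 from WT pachytene to diplotene, -0.25 and -0.30 from WT diplotene to meiosis II, and -0.14 and -0.11 from Cxxc1-null diplotene to meiosis II, and a common median moved it by 0.11 from Cxxc1-null pachytene to diplotene, so shares of higher and lower calls are relative to that shift. Deviations of same-numbered libraries correlated between -0.25 and 0.42 over 15 pairs of groups, with 4, all between genotypes, at or below 0.1. Between the genotypes of the same stage they correlated at -0.066 in pachytene, 0.32 in diplotene and 0.11 in meiosis II. Pairing of the genotypes by replicate number therefore stays open. All 6 pairs within a genotype lay between 0.12 and 0.42, so a shared source of the same-numbered libraries of a genotype stays open. With the replicate number as a block, calls were 66 in pachytene, 140 in diplotene, 1813 in meiosis II, 2695 averaged and 8 for genotype by stage. Depth is unknown beyond its relative value, so changes of genes near 0 FPKM are the least certain.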

Other observations

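The values in this part were chosen after the data were seen and carry no explanation.

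Between diplotene and meiosis II, transcripts known as markers of Sertoli cells and of stress after sorting were higher in both genotypes. All 11 tested Sertoli markers rose in WT (median log2 change 2.28, camera adjusted p = 2.7e-06; adjusted p = 0.23 with an estimated correlation) and all 11 in Cxxc1-null cells. In WT, Inha went from 1.11 ± 0.13 to 30.9 ± 9.5 FPKM, Ctsl from 2.43 ± 0.38 to 59.0 ± 12 FPKM and Clu from 4.07 ± 0.58 to 203 ± 36 FPKM, while Sox9 reached 2.08 ± 0.068 FPKM and Wt1 2.99 ± 0.27 FPKM. Ctsl also had 30.5 ± 12 FPKM in WT pachytene. Of 15 stress response genes 10 rose and 2 fell in WT, with rises such as Nfkbia (2.39 ± 0.21) and Jund (1.47 ± 0.24), with a median of 1.41 (camera adjusted p = 0.03; adjusted p = 0.51 with an estimated correlation). In Cxxc1-null cells 9 rose and 1 fell, with a median of 0.93 (camera adjusted p = 0.046; adjusted p = 0.56 with an estimated correlation).

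Transcripts of the histone replacement genes of late spermatids were not lowest in pachytene. Prm1 had 1020 and 830 FPKM in the WT pachytene libraries, 128 and 305 FPKM in WT diplotene, and 2213 and 3794 FPKM in WT meiosis II, and Tnp1 460 and 341, 54.2 and 112, and 1136 and 1803 FPKM. In the Cxxc1-null libraries Prm1 had 909 and 577 FPKM in pachytene, 29.5 and 185 FPKM in diplotene, and 337 and 1000 FPKM in meiosis II. The genotype difference of Prm1 in meiosis II was -2.32 ± 0.78 and did not pass limma (adjusted p = 0.091).

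By chromosome, 42.0% of X-linked genes rose in the stage-averaged contrast, which takes stages as separate. The share on single autosomes lay between 8.70% and 14.4%, highest on chromosome 14. The median log2 fold change was 0.41 on the X and between 0.01 and 0.09 on the autosomes. All 6 tested genes of the Y chromosome were positive, with a median of 0.68.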
